A study of Homo sapiens with 24 samples.

How the data were processed

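RNA of SH-SY5Y cells was sequenced in 24 libraries, 3 in each of 8 groups: shScramble, shMCART1, oeNC and oeMCART1, each without and with 0.5 mM MPP+ for 24 h. Per the labels, polyadenylated RNA was made into strand-specific libraries. The tissue label reads bone marrow, the metastatic site from which the line was taken, and the growth protocol also names HEK293T cells. The deposited values are TPM, transcript abundances scaled by the authors to the same total in every library, in 1 table for the 12 untreated and 1 for the 12 treated libraries. The aligner, the annotation and whether counting used the strand are not given in the sources used here, so reads of overlapping antisense genes cannot be separated. The submitters' processing notes name the builds GRCm38, mm10 and GRCh38 without a role for each. TPM keep no depth, so the sequencing depth of every library is unknown and no counting interval can be given.

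The untreated table held 63266 entries, of which 25 without a gene identifier were left out, and the treated one held 36783 entries, of which 42 were left out. The tables share 31524 identifiers, or 85.8% of the smaller table. Tests of MPP+ against untreated cells had been planned only for 95% or more, so these 4 comparisons were not run, and levels were only set side by side. Gene locations, transcript GC content and length came from GENCODE 29, which may not be the annotation the authors used. Lowest and highest correlations between replicates of a group were 0.970 and 0.988. Libraries of compared groups with the same replicate number correlated only weakly in their deviations (-0.0729 to 0.211). Other pairs of libraries were not set beside them, so pairing by number is not excluded. No label says whether replicates were separate cultures.

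Values were taken as log2(TPM + 1), and genes at 1 TPM or more in at least 3 libraries of a table were tested with limma 3.58.1 in R 4.3.3 (linear model with a trended empirical Bayes variance, all 4 groups of a table in the fit, all 24 libraries for differences between effects). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SLC25A51 was also tested with a two-sided exact permutation test of TPM. Of 34 gene lists, those with at least 5 measured members were tested with camera, using its preset correlation between genes of 0.01 and, as an alternative, an estimated one, adjusted over the lists. Counts of members were made among all genes and adjusted over the list alone. Tables were prepared with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

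Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. Named were SLC25A51; up to 12 higher and 12 lower genes per comparison (6 and 6 for differences) with the largest log2 change among called genes with an official symbol, a mean of at least 5 TPM in the higher group and groups that did not overlap (the last 2 only within a table); and up to 4 members with the smallest p of each called list and of the lists of complex I, NAD metabolism, ATF4 targets and mitochondrial DNA-encoded mRNAs. Of the genes this rule chose, 3 are not used here, and no others were put in their place. Settings chosen beforehand for comparison were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, leaving out the mitochondrial DNA genes, a replicate block, a robust variance model, library weights, a fit of only the 2 groups compared, and leaving out each library in turn. After the data were seen, removal of each library's trend on transcript GC content (natural spline, 5 degrees of freedom), alone or with that on length, was added. So were, for genes called in 2 comparisons, leaving out each library in turn and fits of only the 2 groups compared.

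The fit was tested on simulated data with 200 changed genes per comparison, 50 per fold. Over the 6 comparisons it recovered 6 to 36% of changes of 1.25-fold, 48 to 92% of 1.5-fold, 78 to 100% of 2-fold and 100% of 4-fold, with 4 (of 14610 genes, untreated knockdown) to 13 (of 15342, the overexpression difference) false calls. For untreated and treated knockdown it recovered 6% and 36% at 1.25-fold, for untreated and treated overexpression 10% and 34%, and for the knockdown and overexpression differences 12% and 8%. These genes were drawn independently of each other, with the same spread in every group and no GC trend. The false calls therefore do not give the error rate in the real libraries, whose replicates also differ along GC content. A GC slope added to the simulated shMCART1 libraries gave 10107 calls, and 0 by limma after removal of the trend. That slope was linear on the same GC values that the removal uses, so 0 was to be foreseen. It checks the working of the removal and cannot tell how much GC bias is removed from the real libraries.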

Results

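The study measured polyadenylated RNA in SH-SY5Y cells, a human neuroblastoma line widely used as a dopaminergic neuron model, in 24 libraries. The cells carried a short hairpin RNA against MCART1 (shMCART1), a scrambled hairpin (shScramble), an MCART1 overexpression construct (oeMCART1) or its control construct (oeNC). MCART1 is the older symbol of SLC25A51, the carrier of the inner mitochondrial membrane that brings NAD+ into the matrix. Each of these was sampled without and with 0.5 mM MPP+, a toxin that blocks respiratory complex I, given for 24 h, and each of the 8 groups held 3 libraries. The deposited values are TPM (transcript abundance scaled to the same total in every library), 1 table for the 12 untreated and 1 for the 12 treated libraries, so the sequencing depth is unknown. Between 13022 and 14306 genes reached 1 TPM per library, the lowest in shMCART1 replicate 3. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between the deposited samples. Values are means ± SD of 3 libraries unless an SE is named.

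The targeted gene was read first, as a check of the labels. SLC25A51 (ENSG00000122696; chromosome 9, 37879400 to 37904353, minus strand, GENCODE 29 on GRCh38) stood at 10.9 ± 0.382 TPM in shScramble and 7.28 ± 2.02 TPM in shMCART1, or 66.5% of the control. With MPP+ it stood at 7.91 ± 0.899 and 5.33 ± 0.423 TPM, or 67.5%. Overexpression raised it from 31.6 ± 3.48 to 683 ± 12.3 TPM without MPP+, and from 8.49 ± 0.837 to 936 ± 69.0 TPM with it, a ratio of 21.6 and of 110. On the log2(TPM + 1) scale the changes were -0.56 ± 0.14 (SE, adjusted p = 0.0195), -0.49 ± 0.09 (0.00239), 4.39 ± 0.14 (2.37e-08) and 6.63 ± 0.09 (1.08e-12). In all 4 comparisons the groups did not overlap, and the two-sided exact permutation test of TPM gave p = 0.1, the smallest that 3 against 3 libraries allow. The untreated knockdown call ended without shScramble replicate 2, shMCART1 replicate 1 or shMCART1 replicate 3 (adjusted p = 0.0811, 0.0518 and 0.0625). The untreated oeNC level lay at 2.89 times that of shScramble, which no label explains.

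**Figure D1:**
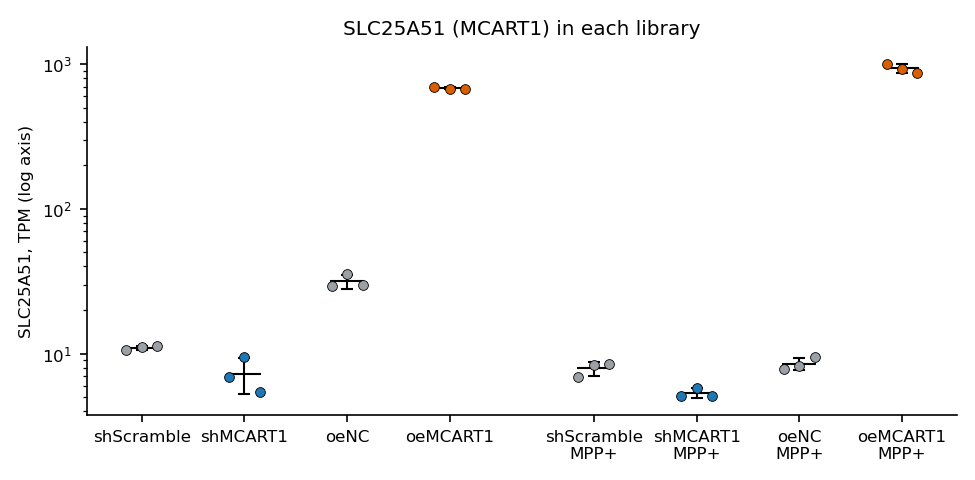
SLC25A51 in each of the 24 libraries, in TPM on a log axis; points are libraries, bars the mean and SD of 3. Libraries of oeMCART1 stood at 683 and 936 TPM on average, and those of shMCART1 at 7.28 and 5.33 TPM, each below its scrambled control.

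The next comparison asked what lower MCART1 does to untreated cells. Of 14703 genes tested, 5035 were called, 1271 higher and 3764 lower in shMCART1. Under median-of-ratios scaling the split was 2643 and 3174, and under quantile normalization 2586 and 2900. The median log2 change of all genes was -0.15, and -0.01 after scaling, so a fall of that size was that of a typical gene. SPARC, a secreted matrix glycoprotein, rose from 4.25 ± 0.697 to 14.5 ± 3.38 TPM (log2 change 1.55 ± 0.19 SE, adjusted p = 0.0134), and DHRS2, a short-chain dehydrogenase, from 3.73 ± 0.459 to 7.70 ± 0.571 TPM. Others among the 12 largest rises were IGSF1 (1.09), GAL3ST1 (0.90), S100A1 (0.84), TMEM63C (0.83) and PLPPR3 (0.81). The largest falls included BAZ1A, a chromatin remodelling subunit (-1.54 ± 0.20 SE), cyclin G1 (CCNG1, -1.47), the actin regulators GMFB (-1.44) and TWF1 (-1.28), the proteasome ATPase PSMC6 (-1.38), the splicing factor MBNL1 (-1.37), the chaperone HSP90AA1 (-1.37; 327 ± 55.5 to 130 ± 42.9 TPM), CCAR1 (-1.29), cyclin C (CCNC, -1.28), NMD3 (-1.28) and the deubiquitinase USP1 (-1.26). SLX1A (1.70), SULT1A1 (0.93) and RGPD5 (-1.55) also ranked there but have near-identical copies, so their reads are uncertain.

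Among gene lists, glycolysis was higher relative to other genes in untreated shMCART1 (camera adjusted p = 0.00656, but adjusted p = 0.995 with an estimated correlation). Of its 23 measured members 8 rose and 3 fell (10 and 4 adjusted over the list alone). ENO2, the neuronal enolase (0.55), PFKL, a phosphofructokinase (0.58), and TPI1 (0.37) rose, and LDHB, a lactate dehydrogenase subunit, fell by 0.75 on the log2 scale. Of the NAD metabolism genes 4 rose and 5 fell out of 23 (4 and 7 adjusted over the list alone), with no list call. QPRT, of the de novo route, rose (0.50), while NAMPT, the rate-limiting enzyme of NAD+ salvage (-0.84), the deacetylase SIRT1 (-1.02) and NUDT12, which hydrolyses NADH (-0.77), fell. Of 37 nuclear complex I subunits 6 rose and 7 fell, among the latter NDUFA5 (-0.91), NDUFS4 (-0.65), NDUFV2 (-0.44) and NDUFA9 (-0.36). Of 17 assembly factors 1 rose, FOXRED1 (0.27), and 4 fell, including TMEM126B (-0.98), TMEM70 (-0.41) and NDUFAF2 (-0.27). Adjusted over the list alone the counts were 6 and 7 for subunits, and 2 and 5 for assembly factors. With GC trends removed, 1 subunit was called, higher, and the list was called upward (median 0.11, camera adjusted p = 0.0027). No mitochondrial DNA-encoded mRNA was called (0 of 13 by limma, also adjusted over the list alone; median -0.27). With GC trends removed their median turned to 0.17, with 1 called higher, and that of assembly factors turned from -0.11 to 0.05. On the deposited values MT-ND5 stood at -0.47, MT-ATP6 at -0.35, MT-ND4 at -0.36 and MT-CO1 at -0.35. The ATF4 and integrated stress response targets had 6 members higher and 11 lower of 38 (7 and 11 adjusted over the list alone), with NARS1 (-0.90), SLC38A2 (-0.89) and CEBPG (-0.81) lower and DDIT4 (0.57) higher.

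These untreated knockdown calls rest on few libraries. Without shScramble replicate 2, limma called 2 genes, CA2 (-1.13) and PHEX-AS1 (1.33), which lie outside the naming rule and were singled out after their values were seen, and none of the 45 called genes named for this comparison. All 45 kept their direction there, with log2 changes 0.778 to 1.33 times those of the full fit (median 0.900 times), and 5108 genes stood at an unadjusted p under 0.05. All 5035 called genes kept their direction too, in a fit that shares its other libraries with the full one. Kept direction therefore adds no separate support. With only the 2 groups in the fit limma called 0, against 5799 at an unadjusted p under 0.05. Such a fit called 7581 genes for untreated overexpression and 4994 and 8439 for treated knockdown and overexpression. Fold changes followed transcript GC content (Spearman 0.777 across genes, which are not independent replicates), and with each library's GC trend removed 1241 genes were called, 493 higher and 748 lower. The calls of SNCG (0.92), TMC6 (0.83), RPH3AL (0.80), RGPD5, LDHB, NUDT12, SLC38A2, CEBPG, DDIT4 and of each named complex I gene above ended there, and NDUFA9 (0.03) and NDUFAF2 (0.29) changed sign, as did the uncalled MT-ATP6 (0.11) and MT-ND4 (0.10). Median-of-ratios scaling ended 4 of the named calls.

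**Figure D2:**
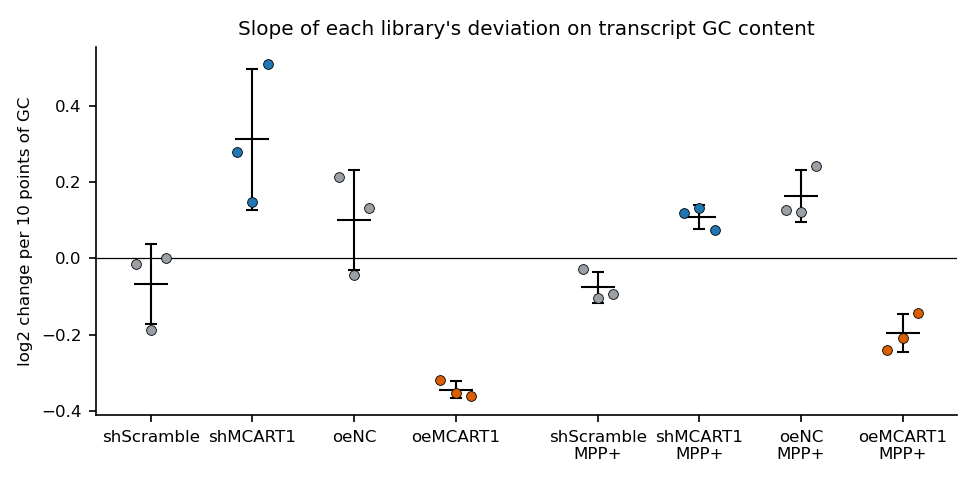
Slope of each library's log2 deviation from the mean of its table on transcript GC content, in log2 units per 10 points of GC; points are libraries, bars the mean and SD of 3. Libraries of shMCART1 and oeMCART1 lie on opposite sides of 0, and untreated libraries of shMCART1, oeNC and shScramble spread widely within their groups.

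The untreated overexpression comparison asked what added MCART1 does without the toxin. Of 14703 genes 7082 were called, 4927 higher and 2155 lower in oeMCART1 (4228 and 3367 under median-of-ratios scaling, which moved the median of all genes from 0.16 to 0.02). Under quantile normalization the majority turned, with 3711 higher and 4014 lower. All 13 mitochondrial DNA-encoded mRNAs, which code for core subunits of complexes I, III, IV and V, fell, with a median of -0.95 (camera adjusted p = 1.19e-09, but adjusted p = 0.641 with an estimated correlation; 13 lower adjusted over the list alone). MT-ND2 fell from 2051 ± 295 to 893 ± 99.7 TPM (-1.19 ± 0.20 SE, adjusted p = 0.0041) and MT-ND1 from 1619 ± 292 to 708 ± 60.8 TPM (-1.18). MT-CO2, MT-CYB (-0.96) and MT-ND3 (-0.95) fell likewise, as did MT-ATP8 (-1.16) and MT-ATP6 (-0.98), whose reading frames overlap so that their reads are uncertain. The 13 mRNAs made up 8.70 ± 1.09% of TPM in oeNC, 4.44 ± 0.508% in oeMCART1, 4.90 ± 0.266% in shScramble and 4.58 ± 0.638% in shMCART1, so oeNC stood apart from the other untreated groups.

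Next to SLC25A51 itself, the largest rises with overexpression were RPAP2, an RNA polymerase II phosphatase, the helicases DHX29 (1.48 ± 0.17 SE) and ASCC3 (1.39), PIGK (1.42), HSP90AA1 (1.41; 217 ± 46.5 to 569 ± 22.5 TPM), ZFP90 (1.41), TRMT10A (1.39) and WDR75 (1.36). The small nuclear RNAs RNU1-1 and RNU1-2 also ranked there; they were listed at 0 in every oeNC library, are near-identical and are not polyadenylated, so they are uncertain. Lower were the transcription cofactor LBH (-1.01), ISYNA1, which makes inositol phosphate (-0.99), B4GALNT4 (-0.90) and the small Cajal body RNAs SCARNA12 (-1.59) and SCARNA13 (-1.12). Like RNU1-1 and RNU1-2, these small RNAs are not polyadenylated, and so uncertain. Glycolysis was lower relative to other genes (camera adjusted p = 0.00415, adjusted p = 0.641 with an estimated correlation), with 11 of 23 members lower and 3 higher, the same counts adjusted over the list alone. PFKFB4 (-0.67), PKM (-0.45) and ENO1 (-0.42) fell, and the lactate transporter SLC16A1 rose (1.03). Immediate early genes, which respond within minutes to growth and stress signals, were lower (camera adjusted p = 0.011, adjusted p = 0.641 with an estimated correlation), 5 lower and 1 higher of 16 (5 and 1 adjusted over the list alone): FOSB (-1.25), FOS (-0.69) and NR4A1 (-0.64) fell and KLF6 rose (0.56).

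Without a list call, 11 of 17 complex I assembly factors rose and 3 fell (11 and 3 adjusted over the list alone), among them TMEM126B (0.97), NUBPL (0.94), NDUFAF1 (0.59) and TMEM70 (0.59). After GC correction 5 were higher and 1 lower, and their median went from 0.40 to 0.0184. Nuclear complex I subunits went both ways, 10 higher and 11 lower of 37 (10 and 12 adjusted over the list alone), with NDUFS4 (0.86), NDUFB5 (0.82) and NDUFS1 (0.78) higher and NDUFS7 (-0.64) lower. With GC trends removed, 1 subunit was higher and 9 lower, and the list was called downward (median -0.14, camera adjusted p = 0.000771). Of the NAD metabolism genes 9 rose and 6 fell (9 and 7 adjusted over the list alone), with SIRT1 (0.99), NUDT12 (0.94), NAMPT (0.93) and NNT (0.89) higher. ATF4 and integrated stress response targets counted 14 higher and 8 lower of 38 (15 and 8 adjusted over the list alone), with XPOT (1.04), ALDH1L2 (1.03), NARS1 (1.03) and CEBPG (0.90) higher. Fold changes followed GC content (Spearman -0.801 across genes), and with GC trends removed 2305 genes were called. The calls of TRMT10A, SCARNA12, FOS, NDUFS4, NDUFB5, TMEM126B, NNT, CEBPG and XPOT and the immediate early list call ended there, while the 13 mitochondrial mRNAs fell further (median -1.39). On the deposited values without oeNC replicate 1, the count of called genes was 3989, and 6 of 47 named calls ended. Without oeMCART1 replicate 2 or replicate 3, 5 or 4 of the 47 ended.

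**Figure D3:**
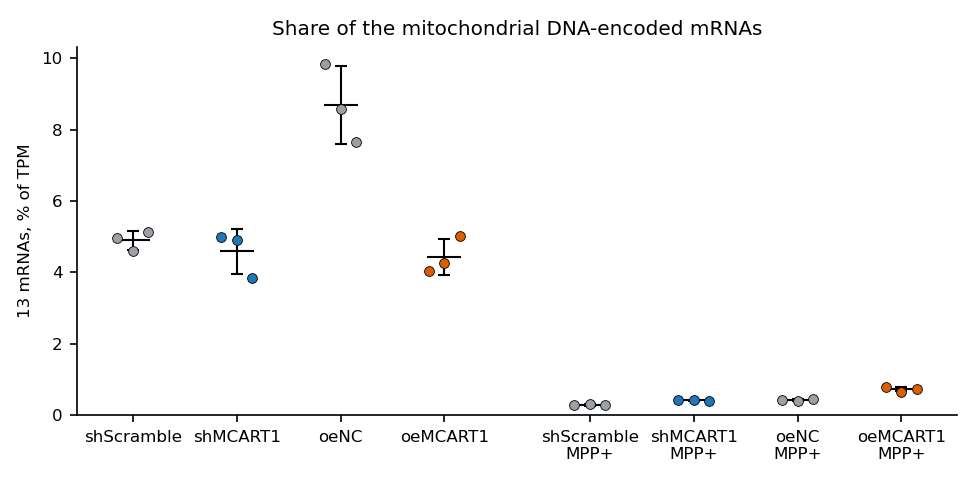
Share of TPM held by the 13 mitochondrial DNA-encoded mRNAs, in percent, in each library; points are libraries, bars the mean and SD of 3. The untreated oeNC libraries averaged 8.70% and the other untreated groups 4.44% to 4.90%; with MPP+ every group averaged under 1%, from 0.285% in shScramble to 0.724% in oeMCART1.

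With MPP+, the knockdown comparison asked how lower MCART1 alters cells under complex I stress. Of 14895 genes 4924 were called, 1616 higher and 3308 lower in shMCART1, or 2481 and 2354 under median-of-ratios scaling and 2373 and 2479 under quantile normalization. Of the called lists, that with the most members called was ATF4 and integrated stress response targets, the amino acid and redox genes switched on by mitochondrial and nutrient stress: 28 of 40 were lower and 3 higher (28 and 3 adjusted over the list alone; camera adjusted p = 1.12e-07, but adjusted p = 0.0574 with an estimated correlation), with a median of -0.41. GDF15, a stress-secreted cytokine, fell from 28.8 ± 2.71 to 11.4 ± 1.85 TPM (-1.28 ± 0.12 SE, adjusted p = 6.87e-05), CHAC1, which degrades glutathione, from 56.6 ± 1.59 to 23.8 ± 2.51 TPM (-1.22), TRIB3 from 180 ± 10.2 to 90.8 ± 6.32 TPM (-0.98), and WARS1, a tRNA synthetase, from 339 ± 3.82 to 204 ± 2.53 TPM (-0.73). The serine enzyme PSPH (-0.97) and the cystine transporter SLC7A11 (-1.13) fell as well. Immediate early genes rose, 10 of 15 with 0 lower by limma (0 also adjusted over the list alone; 0 lower at an unadjusted p under 0.05; camera adjusted p = 4.31e-08, adjusted p = 0.0924 with an estimated correlation). JUN rose from 120 ± 14.3 to 350 ± 52.5 TPM (1.54 ± 0.18 SE), with IER3 (0.89), NR4A1 (0.73) and IER2 (0.56).

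The largest rises under the naming rule were ADAMTS1, a matrix metalloprotease (31.3 ± 2.87 to 135 ± 7.12 TPM, 2.08 ± 0.15 SE, adjusted p = 1.86e-05), and the small GTPase RHOB (2.04). CCN1, a matrix signal (1.71), DUSP1, a phosphatase that switches off MAP kinases (1.61), SPARC (1.47), the kinase PIM1, ATF3 (1.21), MAFF (1.13), BHLHE40 (1.12) and SAT1, of polyamine breakdown (1.11), followed. The largest falls were MAT2A, which makes S-adenosylmethionine (-1.71 ± 0.19 SE), ERI2 (-1.60), PLEKHG2 (-1.60), MTHFS, of folate metabolism (-1.55), NCOA5 (-1.48), EIF4EBP2, a brake on translation (-1.46), TMEM135 (-1.44) and the RNA gene ACAD9-DT (-1.40). The histone genes H4C8 (-1.62) and H4C1 (-1.46) are near-identical and not polyadenylated, and so uncertain.

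Mitochondrial DNA-encoded mRNAs were higher in treated shMCART1, 10 of 13 with 0 lower by limma (10 and 0 adjusted over the list alone; 0 lower at an unadjusted p under 0.05; median 0.59, camera adjusted p = 6.95e-08, adjusted p = 0.269 with an estimated correlation). MT-ND1 stood at 286 ± 10.7 against 150 ± 18.2 TPM (0.94). MT-CO2 (0.87), MT-CO3 (0.78) and MT-ND4 (0.62) were also higher. Treated shScramble stood lowest in these mRNAs, at 0.285 ± 0.0236% of TPM, while shMCART1 (0.418 ± 0.0162%) stood near the other control, oeNC (0.421 ± 0.0315%). Nuclear subunits of complexes II to V rose by less, 18 higher and 4 lower of 41 (18 and 4 adjusted over the list alone; camera adjusted p = 1.9e-05, adjusted p = 0.0699 with an estimated correlation). Among them were ATP5MC1 (0.40), COX6B1 (0.38), COX7A2 (0.36) and COX7C (0.22). Complex I subunits counted 6 higher and 5 lower of 37, the same adjusted over the list alone. NDUFA2 (0.43), NDUFA1 (0.37) and NDUFA10 (0.26) were higher and NDUFC2 (-0.40) lower. Removing GC trends gave 11 higher and 2 lower, and a list call upward (camera adjusted p = 0.023). Assembly factors counted 3 higher and 6 lower of 17, the same adjusted over the list alone. COA1 (0.33) and ECSIT (0.26) were higher and TMEM126B (-0.65) and TMEM70 (-0.63) lower. Their median of -0.10 turned to 0.10 with GC trends removed. Of NAD metabolism genes QPRT rose (0.65) and 6 fell, the same counts adjusted over the list alone, among them SARM1, the axonal NAD+ hydrolase (-0.63), NMRK1 (-0.35) and PARP2 (-0.25).

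Glycolysis was higher again, 8 of 23 higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.00101, adjusted p = 0.47 with an estimated correlation). Among them were SLC2A3 (0.70), ENO2 (0.57), ALDOC (0.48) and PFKL (0.40). Cholesterol synthesis genes rose, 9 higher and 2 lower of 22 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.269 with an estimated correlation). INSIG1, which holds the sterol sensor in the endoplasmic reticulum, rose from 28.0 ± 1.74 to 64.7 ± 5.38 TPM (1.18), with MVD (0.43) and DHCR7 (0.39). Targets of p53 fell, 10 lower and 2 higher of 22 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0232, adjusted p = 0.269 with an estimated correlation). Among them were SESN1 (-0.80), CDKN1A (-0.74), TNFRSF10B (-0.47) and AEN (-0.32). Mesenchymal markers of neuroblastoma, a sign of another cell state of this line, were higher (6 higher and 2 lower of 19, 8 and 3 adjusted over the list alone; camera adjusted p = 0.0482, adjusted p = 0.554 with an estimated correlation). CCN1, COL3A1 (0.80) and TWIST1 (0.41) were higher and ANXA1 (-0.95) lower. Nuclear and long noncoding RNAs taken as a sign of RNA quality were lower, 4 of 5 with 0 higher by limma (4 and 0 adjusted over the list alone; 0 higher at an unadjusted p under 0.05; camera adjusted p = 0.00984, adjusted p = 0.459 with an estimated correlation). These were ZFAS1 (-0.53), GAS5 (-0.42), NEAT1 (-0.42) and SNHG1 (-0.29). Whether they follow RNA quality in these cells was not tested. Fold changes followed GC content (Spearman 0.484 across genes), and with GC trends removed 3859 genes were called. The calls of TMEM135, PARP2, NMRK1 and SNHG1 and of the mesenchymal and noncoding RNA lists ended there (camera adjusted p = 0.0592 and 0.0654; mesenchymal 0.0809 under median-of-ratios scaling), and ACAD9-DT had no GC value.

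The treated overexpression comparison asked what added MCART1 does under complex I stress. Of 14895 genes 9067 were called, 6949 higher and 2118 lower in oeMCART1; median-of-ratios scaling made this 4214 and 4099 and moved the median of all genes from 0.26 to 0.02. Quantile normalization gave 4147 and 3930. Targets of p53, the genes of cell cycle arrest and death induced by that factor, rose in 18 of 22 cases with 0 lower by limma (18 and 0 adjusted over the list alone; 0 lower at an unadjusted p under 0.05; median 1.06, camera adjusted p = 0.000425, but adjusted p = 0.107 with an estimated correlation). SESN1 rose from 5.96 ± 0.751 to 23.7 ± 1.83 TPM (1.83 ± 0.10 SE, adjusted p = 2.96e-07), the death receptor TNFRSF10B from 39.0 ± 3.49 to 81.1 ± 1.70 TPM (1.04), BTG2 by 0.96 and AEN by 0.55. Genes of the unfolded protein response of the endoplasmic reticulum rose in 17 of 20 cases with 0 lower by limma (17 and 0 adjusted over the list alone; 0 lower at an unadjusted p under 0.05; camera adjusted p = 4.12e-05, adjusted p = 0.206 with an estimated correlation). Among them were MANF (0.83), PDIA3 (0.70), SEC61B (0.69) and XBP1 (0.61). Cytosolic ribosomal protein genes fell, 51 lower and 9 higher of 82 (53 and 9 adjusted over the list alone; camera adjusted p = 8.44e-18, and adjusted p = 0.0448 with an estimated correlation). RPL7A fell from 7508 ± 141 to 4259 ± 44.2 TPM (-0.82), with RPL13A (-0.63), RPL3 (-0.57) and RPS3 (-0.55). The treated oeNC control stood highest in these genes, at 46.0 ± 0.307% of TPM, against 42.5 ± 0.723% in shScramble and 43.1 ± 0.194% in shMCART1, with oeMCART1 the lowest, so the fall is against a control that itself stood apart.

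Cholesterol synthesis genes fell, 11 lower and 5 higher of 22 (11 and 5 adjusted over the list alone; camera adjusted p = 5.59e-05, adjusted p = 0.107 with an estimated correlation). INSIG1 fell from 43.2 ± 11.2 to 6.63 ± 0.324 TPM (-2.50 ± 0.14 SE), MVD by 1.05, DHCR7 by 0.77 and FDFT1 by 0.65 on the log2 scale. Glycolysis was lower, 14 lower and 4 higher of 23, the same adjusted over the list alone (camera adjusted p = 8.18e-06, adjusted p = 0.254 with an estimated correlation). The glucose transporter SLC2A3 (-1.45), ENO2 (-0.71) and HK1 (-0.46) were lower and SLC16A1 (1.04) higher. Immediate early genes were lower, 8 lower and 1 higher of 15, the same adjusted over the list alone (camera adjusted p = 5.59e-05, adjusted p = 0.226 with an estimated correlation). Among them were NR4A1 (-1.24), IER3 (-1.02), JUNB (-0.81) and MYC (-0.59). Mesenchymal markers were lower, 6 lower and 2 higher of 19, the same adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.489 with an estimated correlation). COL1A1 (-1.73), COL3A1 (-0.92) and NOTCH3 (-0.75) were lower and YAP1 (0.77) higher.

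The largest falls in treated oeMCART1 were LBH (27.0 ± 2.37 to 2.77 ± 0.365 TPM, -2.89 ± 0.10 SE, adjusted p = 1.08e-08), INSIG1 and TSC22D3, a glucocorticoid-induced leucine zipper (-1.93). PLPPR3 (-1.64), ANKRD37 (-1.59), the actin bundler FSCN1 (-1.56), the retinoic acid carrier CRABP2 (-1.52), HBQ1 (-1.50), USH1C (-1.47) and EFNA3 (-1.47) followed. The largest rises next to SLC25A51 were INPP5D, a lipid phosphatase (1.10 ± 0.243 to 9.45 ± 0.806 TPM, 2.32 ± 0.12 SE), smooth muscle actin ACTA2 (1.88), FAM13B (1.83), MTHFS (1.82), DLEU2 (1.82), ZNF326 (1.80), the splicing factor SRSF6 (1.78), the mitochondrial nuclease EXOG (1.78), the chaperone HSPH1 (1.77) and SH3BGR (1.76).

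For mitochondria, 53 of 78 mitochondrial ribosomal protein genes were higher and 7 lower (53 and 8 adjusted over the list alone; camera adjusted p = 0.0282, adjusted p = 0.559 with an estimated correlation). Among them were MRPS35 (0.94), MRPL3 (0.80), MRPL40 (0.65) and MRPL18 (0.62). Under median-of-ratios scaling the list's test turned downward and its median was 0.01. Mitochondrial DNA-encoded mRNAs had 9 members higher and 2 lower of 13, the same adjusted over the list alone, without a list call (camera adjusted p = 0.29). MT-ATP6 (1.52), MT-ATP8 (1.39), MT-ND4 (0.95) and MT-ND4L (0.95) were higher, both overlapping pairs being uncertain. Complex I subunits counted 19 higher and 3 lower of 37 (20 and 3 adjusted over the list alone) and assembly factors 12 higher and 1 lower of 17 (12 and 1 adjusted over the list alone), neither with a list call. NDUFC2 (0.77), NDUFS4 (0.64), NDUFB2 (0.64), NDUFC1 (0.55), TMEM126B (1.13), NDUFAF8 (0.97), NDUFAF6 (0.95) and NDUFAF1 (0.49) rose. After removal of GC trends 6 assembly factors were higher and 4 lower (median -0.03, from 0.44), and 3 mitochondrial mRNAs were higher and 3 lower (median 0.04, from 0.47). NAD metabolism counted 9 higher and 3 lower of 23, the same adjusted over the list alone: SIRT1 (0.91), NADK2 (0.83) and SARM1 (0.43) rose and QPRT (-0.60) fell. ATF4 and integrated stress response targets counted 26 higher and 10 lower of 40, the same adjusted over the list alone (camera adjusted p = 0.3). SLC7A11 (1.37), CEBPG (1.15), WARS1 (0.88) and SLC7A1 (0.57) were higher. Fold changes followed GC content (Spearman -0.603 across genes), and with GC trends removed 6622 genes were called. Calls of at least 1.5-fold numbered 4465 on the deposited values and 1783 with those trends removed. The calls of NDUFS4, NDUFAF1, MT-ND4L, NADK2, SIRT1, YAP1 and the mitochondrial ribosome list ended there.

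**Figure D4:**
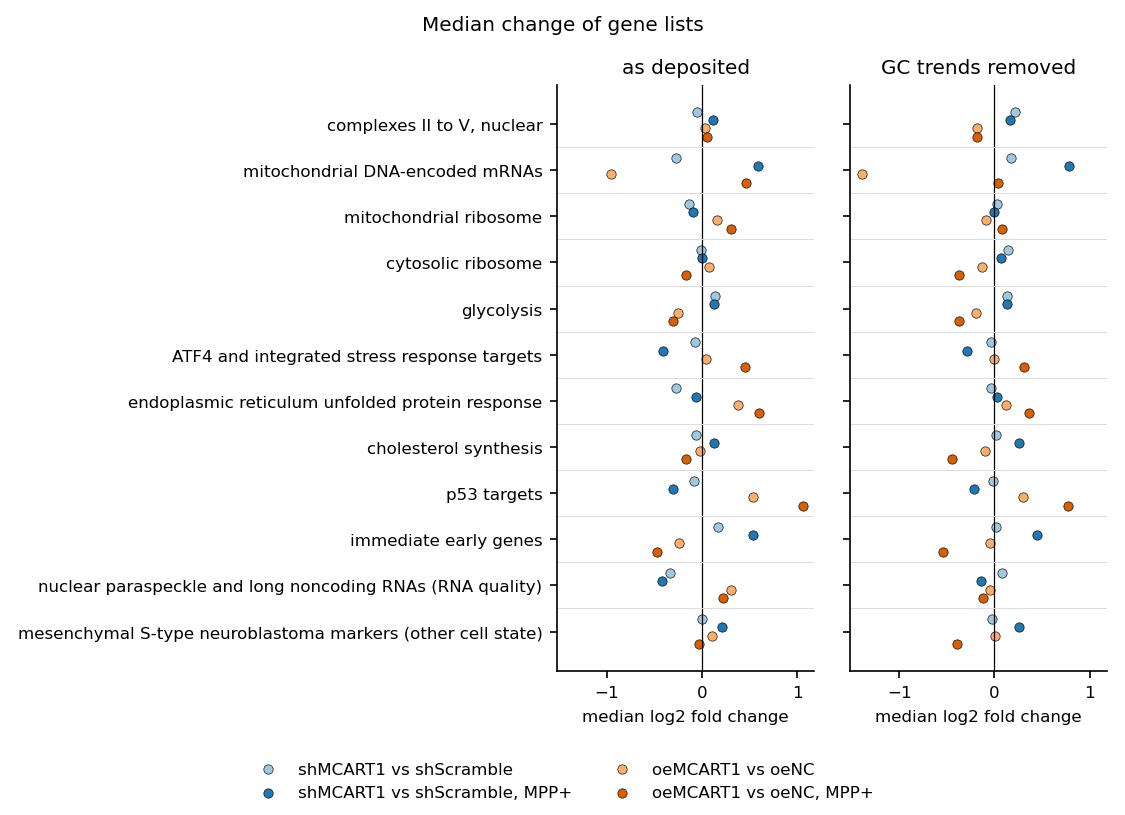
Median log2 fold change of the 12 gene lists called in at least 1 of 4 comparisons, on the deposited values (left) and with each library's GC trend removed (right); each point is 1 list in 1 comparison. In untreated oeMCART1 the mitochondrial DNA-encoded mRNAs had a median of -0.95, and in treated cells p53 targets had a median of 1.06 with overexpression and -0.31 with knockdown.

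The difference between the knockdown effects with and without MPP+ was tested over all 24 libraries. Of 15653 genes 605 were called, 269 with a higher and 336 with a lower effect under MPP+; the majority turned with library weights (2789 and 1830) and without untreated shMCART1 replicate 2 (1641 and 823). ATF4 and integrated stress response targets had a lower knockdown effect under MPP+ in 17 of 40 cases and a higher one in 2 (21 and 2 adjusted over the list alone; camera adjusted p = 1.52e-10, and adjusted p = 0.0298 with an estimated correlation). NUPR1 (-1.53 ± 0.27 SE, adjusted p = 0.00438), CHAC1 (-1.36), SESN2 (-1.33), TRIB3 (-1.32) and GDF15 (-1.31) were among the 6 lowest under the naming rule. Mitochondrial DNA-encoded mRNAs differed upward in 9 of 13 (10 adjusted over the list alone; camera adjusted p = 2.02e-07, adjusted p = 0.47 with an estimated correlation). MT-ND1 stood at 1.03 and MT-CO3 at 0.93, and the low treated shScramble level of these mRNAs entered here. Immediate early genes differed upward in 5 of 16 (7 up and 1 down adjusted over the list alone; camera adjusted p = 0.00131, adjusted p = 0.337 with an estimated correlation). JUN led them (1.61 ± 0.21 SE) and KLF6 (1.44). Cholesterol synthesis genes differed upward in 4 of 22 and downward in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00434, adjusted p = 0.337 with an estimated correlation). INSIG1 led them (1.73). Targets of p53 differed downward in 2 of 22 (8 down and 2 up adjusted over the list alone; camera adjusted p = 0.00131, adjusted p = 0.185 with an estimated correlation), CDKN1A (-1.05) and AEN (-0.44). In NAD metabolism 1 of 23 differed upward and 1 downward (3 and 1 adjusted over the list alone), NAMPT (0.77) and SARM1 (-0.65), and the complex I lists had 1 upward call each, NDUFS5 (0.46) and COA1 (0.37), also adjusted over the list alone, where 1 assembly factor also differed downward. The tables were deposited apart, so a difference between them that acts unlike on knockdown and control libraries would enter these values. The count moved by over 1.5 times when single libraries were left out, from 265 without shScramble replicate 3 with MPP+ to 2464 without untreated shMCART1 replicate 2, and to 1114 with GC trends removed, where FDFT1 (0.34) and COA1 lost their calls. SLC25A51 itself had a like knockdown effect with and without MPP+ (difference 0.07 ± 0.18 SE, adjusted p = 0.841).

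For overexpression the same difference was called for 2787 of 15653 genes, 1967 upward and 820 downward, or 996 and 1461 under median-of-ratios scaling and 1406 and 1163 under quantile normalization. All 13 mitochondrial DNA-encoded mRNAs differed upward, also adjusted over the list alone (median 1.33; camera adjusted p = 1.37e-13, adjusted p = 0.119 with an estimated correlation). MT-CO2 differed by 1.47 ± 0.18 SE (adjusted p = 1.64e-05), as did MT-CO3 (1.36) and the overlapping MT-ATP8 (2.55), MT-ATP6 (2.50) and MT-ND4L (1.71). Without MPP+ the median of oeMCART1 was -0.95 against oeNC but -0.03 against shScramble, with oeNC at 0.84 against shScramble. By medians, most of the difference of 1.33 thus rests on the high untreated oeNC level of these mRNAs. That does not hold for every member, since MT-ATP6 stood at -0.98 without MPP+, with a difference of 2.50. SLC25A51 differed by 2.23, its oeNC level being higher (31.6 against 8.49 TPM) and its oeMCART1 level lower (683 against 936 TPM) without MPP+. Nuclear complex I subunits differed upward in 13 of 37 and downward in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000916, adjusted p = 0.0517 with an estimated correlation). Among them were NDUFB2 (0.77), NDUFC1 (0.66) and NDUFC2 (0.66). Mitochondrial ribosomal genes differed upward in 28 of 78 and downward in 3 (30 and 3 adjusted over the list alone; camera adjusted p = 0.00329, adjusted p = 0.225 with an estimated correlation). MRPL28 led them (0.82). Cytosolic ribosomal genes differed downward in 38 of 82 with 0 upward by limma (45 down and 2 up adjusted over the list alone; camera adjusted p = 2.3e-18, and adjusted p = 0.00951 with an estimated correlation). RPL3 (-0.82) and RPL7A (-0.65) were among them, and the high treated oeNC level of these genes entered here too. Cholesterol synthesis genes differed downward in 10 of 22 and upward in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 4.68e-07, and adjusted p = 0.0414 with an estimated correlation). INSIG1 (-2.75 ± 0.18 SE) and SREBF2 (-0.68) were among them.

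In the same overexpression difference, p53 targets differed upward in 9 of 22 (10 up and 1 down adjusted over the list alone; camera adjusted p = 0.000807, adjusted p = 0.0839 with an estimated correlation). TP53I3 (1.65), BAX (0.97) and TNFRSF10B (0.80) were among them. Genes of the unfolded protein response of the endoplasmic reticulum differed upward in 7 of 20, also adjusted over the list alone (camera adjusted p = 0.000986, adjusted p = 0.429 with an estimated correlation). CRELD2 (0.64) and XBP1 (0.58) were among them. ATF4 and integrated stress response targets differed upward in 12 of 40 and downward in 4 (14 and 5 adjusted over the list alone; camera adjusted p = 0.0352, adjusted p = 0.429 with an estimated correlation). SESN2 (1.46), SLC7A5 (0.90) and WARS1 (0.79) were among them. HIF-1 targets outside glycolysis, induced by low oxygen, differed downward in 5 of 17 (6 adjusted over the list alone; camera adjusted p = 0.000285, adjusted p = 0.357 with an estimated correlation). These included ANKRD37 (-1.62), NDRG1 (-0.90), CA12 (-0.64) and MXI1 (-0.60). Mesenchymal markers differed downward in 4 of 19 (6 adjusted over the list alone; camera adjusted p = 0.00255, adjusted p = 0.357 with an estimated correlation). These were COL1A1 (-1.54), CCN1 (-1.04), COL3A1 (-0.92) and SOX9 (-0.63). In NAD metabolism 3 differed upward and 4 downward of 23, the same adjusted over the list alone, with SIRT7 (0.86) and SARM1 (0.70) up and NAMPT (-0.88) and NMRK1 (-0.81) down, and of 17 complex I assembly factors 2 differed upward and 1 downward, the same adjusted over the list alone: NDUFAF8 (0.71), FOXRED1 (0.41) and COA1 (-0.40). Under median-of-ratios scaling the complex I subunit, mitochondrial ribosome and ATF4 list calls ended (camera adjusted p = 0.212, 0.311 and 0.119). Quantile normalization ended 3 of the 10 list calls of this difference, and the filter of 5 TPM and the pseudocount of 0.1 ended 1 each. Of the 36 list calls in the 6 comparisons, 4 held with an estimated correlation: ATF4 targets in the knockdown difference, cytosolic ribosome with treated overexpression and in its difference, and cholesterol synthesis in that difference. For each of the 36, median, mean and test had the same sign. The lists of complex I, NAD metabolism, ATF4 targets and mitochondrial mRNAs were reported whether called or not, and some of them differed there, since camera is relative to all other genes. Its test ran against both median and mean for NAD metabolism and ATF4 targets in both untreated comparisons, NAD metabolism in treated oeMCART1 and complex I subunits in the knockdown difference. Median and mean differed in sign for complex I subunits in untreated shMCART1 (0.05 and -0.03) and untreated oeMCART1 (-0.0096 and 0.02), NAD metabolism in treated shMCART1 (0.01 and -0.04) and assembly factors in the knockdown difference (-0.02 and 0.06).

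Knockdown and overexpression were then compared for genes called in both. Without MPP+, 4114 genes were called in opposite directions and 7 in the same direction, where independent lists would share 186 genes higher with knockdown and lower with overexpression and 1261 the other way round. HSP90AA1, SIRT1, NAMPT and NARS1 are examples, each lower with knockdown and higher with overexpression. Leaving out 1 library at a time, chosen for these overlaps after the data were seen, gave 1 to 5743 opposite genes: 1930 without shMCART1 replicate 1, 878 without shMCART1 replicate 3, 2680 without shScramble replicate 1 and 1 without shScramble replicate 2 (4135 at an unadjusted p under 0.05 in both). With only the 2 groups of each comparison in its fit, limma left 0 (4870 unadjusted). With GC trends removed 581 genes were called in opposite directions and 10 in the same direction, against 39.1 and 62.5 opposite for independent lists. With MPP+, 3906 were opposite and 170 the same (2545 and 165 with GC trends removed), INSIG1, SESN1, WARS1, SARM1, QPRT and SLC2A3 among the opposite. By independence 230 would be higher with knockdown and lower with overexpression, and 1543 the other way round (403 and 518 with GC trends removed). Genes called lower with knockdown under MPP+ were higher as a set with overexpression (camera adjusted p = 2.34e-37, and adjusted p = 0.0223 with an estimated correlation); without MPP+ that call was lost (3.94e-67, adjusted p = 0.0677 with an estimated correlation). The libraries of the 2 arms share no controls, but both arms of a table share 1 estimate of each gene's spread. Calls in both arms can therefore coincide more often than in independent lists, whatever their direction. Of genes called with and without MPP+, 2399 had the same knockdown direction, SPARC, ENO2, PFKL and QPRT among them, and 61 the opposite; for overexpression 4801 had the same direction, LBH, SLC16A1 and SIRT1 among them, and 475 the opposite. Without 1 library the shared knockdown genes numbered 1 to 3025: 1281 without untreated shMCART1 replicate 1, 645 without untreated shMCART1 replicate 3 and 1 without untreated shScramble replicate 2 (2867 unadjusted). Limma left 0 with only the 2 groups of each comparison (3274 unadjusted). For overexpression they numbered 2908, without untreated oeNC replicate 1, to 5239. Independent lists would share 142 genes higher and 865 lower for knockdown, and 2336 and 317 for overexpression. With GC trends removed, 552 had the same knockdown direction and 18 the opposite, and 1136 and 237 for overexpression.

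Effects of MPP+ itself were set side by side without a test, since the 2 tables share too few identifiers. The 13 mitochondrial DNA-encoded mRNAs stood far lower in the treated table: MT-CO3 was at 5190 ± 229 TPM in untreated and 79.5 ± 2.49 TPM in treated shScramble. Their median log2 difference was -4.05 in shScramble, -3.07 in shMCART1, -4.13 in oeNC and -1.98 in oeMCART1. ATF4 and integrated stress response targets stood higher, with a median difference of 1.05 in shScramble, 0.82 in shMCART1, 1.11 in oeNC and 1.32 in oeMCART1. The 5 nuclear and long noncoding RNAs taken as a sign of RNA quality stood higher as well, their medians ranging from 1.02 in oeMCART1 to 1.70 in shMCART1. Whether they follow RNA quality here was not tested. In shScramble DDIT3, a death-promoting transcription factor, stood at 11.3 ± 0.801 and 162 ± 6.67 TPM, TRIB3 at 16.1 ± 1.57 and 180 ± 10.2 TPM, and asparagine synthetase ASNS at 139 ± 3.97 and 666 ± 20.4 TPM. Cholesterol synthesis genes stood lower (median -0.78 in shScramble, -0.40 in shMCART1, -0.51 in oeNC and -1.08 in oeMCART1), with HMGCS1 at 36.2 ± 4.66 and 12.9 ± 0.302 TPM in shScramble. Ribosomal protein genes held 31.1 ± 0.989% of TPM in untreated and 42.5 ± 0.723% in treated shScramble. These values mix the toxin's effect with any difference in how the tables were made.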

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

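Tests of GC content, transcript length, oeNC levels and even carry-over were chosen only after the result was seen. The results here are differences between 2 effects, that under MPP+ minus that without it, tested by the contrast of contrasts over 24 libraries.

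For knockdown 605 genes differed. ATF4 and integrated stress response targets, induced by mitochondrial stress, differed downward (median log2 difference -0.27; adjusted p = 0.0298 with an estimated correlation): NUPR1 -1.53, CHAC1 -1.36, SESN2 -1.33, TRIB3 -1.32, GDF15 -1.31, SLC7A5 -0.73 and SLC3A2 -0.59. Mitochondrial DNA-encoded mRNAs differed upward (median 0.83, but camera adjusted p = 0.47 with an estimated correlation): MT-ND1 1.03, MT-CO2 0.98, MT-ND4 0.98 and MT-CO3 0.93. Treated shScramble stood apart here, with 0.285% of TPM in these mRNAs against 0.418% in treated shMCART1 and 0.421% in treated oeNC. Immediate early genes differed upward in 5 of 16 (median 0.35, but adjusted p = 0.337 with an estimated correlation), with JUN 1.61, KLF6 1.44, ATF3 1.10 and MYC 0.75. Cholesterol synthesis genes had a median of 0.26 (adjusted p = 0.337 with an estimated correlation), with INSIG1 1.73, IDI1 1.24 and FDFT1 0.34 upward and PMVK -0.59 downward. Targets of p53 had a median of -0.27 (adjusted p = 0.185 with an estimated correlation), with CDKN1A -1.05 and AEN -0.44. Other genes were PHTF2 (1.89), RHOB (1.82), ADAMTS1 (1.62), the transcription factor SOX4 (1.46), NAMPT (0.77), NDUFS5 (0.46) and COA1 (0.37) upward, and NCOA5 (-1.32) and SARM1 (-0.65) downward.

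For overexpression 2787 genes differed. Mitochondrial DNA-encoded mRNAs differed upward (median 1.33, but adjusted p = 0.119 with an estimated correlation), with MT-ATP8 2.55, MT-ATP6 2.50, MT-ND4L 1.71, MT-CO2 1.47 and MT-CO3 1.36. Untreated oeNC stood apart here, with 8.70% of TPM in mitochondrial DNA genes against 4.44 to 4.90% in the other untreated groups. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4, so the split between them is uncertain. Nuclear complex I subunits had a median of 0.22 (adjusted p = 0.0517 with an estimated correlation, and 0.212 under median-of-ratios scaling), with NDUFB2 0.77, NDUFC1 0.66, NDUFC2 0.66 and NDUFB9 0.46. The assembly factors NDUFAF8 (0.71) and FOXRED1 (0.41) differed upward and COA1 (-0.40) downward. Mitochondrial ribosomal genes (median 0.17; adjusted p = 0.225 with an estimated correlation, and 0.311 under median-of-ratios scaling) included MRPL28 0.82, MRPS7 0.51, MRPL40 0.46 and MRPL21 0.44. Cytosolic ribosomal genes differed downward (median -0.23; adjusted p = 0.00951 with an estimated correlation), with RPS25 -0.91, RPL3 -0.82, RPS23 -0.69 and RPL7A -0.65. Cholesterol synthesis genes had a median of -0.50 (adjusted p = 0.0414 with an estimated correlation), with INSIG1 -2.75, SREBF2 -0.68 and FDFT1 -0.63.

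In the same overexpression difference p53 targets had a median of 0.49 (adjusted p = 0.0839 with an estimated correlation), with TP53I3 1.65, BAX 0.97, TNFRSF10B 0.80 and BTG2 0.67. ATF4 targets had a median of 0.19 (adjusted p = 0.429 with an estimated correlation, and 0.119 under median-of-ratios scaling), with SESN2 1.46, SLC7A5 0.90, WARS1 0.79 and SLC3A2 0.74. Genes of the endoplasmic reticulum's unfolded protein response had a median of 0.26 (adjusted p = 0.429 with an estimated correlation), with CRELD2 0.64, XBP1 0.58, MANF 0.51 and SEC61B 0.45. HIF-1 targets had a median of -0.38 (adjusted p = 0.357 with an estimated correlation), with ANKRD37 -1.62, NDRG1 -0.90, CA12 -0.64 and MXI1 -0.60. Mesenchymal markers had a median of -0.23 (adjusted p = 0.357 with an estimated correlation), with COL1A1 -1.54, CCN1 -1.04, COL3A1 -0.92 and SOX9 -0.63. Further differences were SLC25A51 2.23, INPP5D 1.65, SIRT7 0.86 and SARM1 0.70 upward, and LBH -1.88, SLC2A3 -1.64, BHLHE40 -1.63, NAMPT -0.88 and NMRK1 -0.81 downward.

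Chance was not excluded for these counts by exchanging labels. Of 100 splits drawn from 200, 8 gave 605 or more genes for knockdown and 7 gave 2787 or more for overexpression, the highest others giving 7705 and 9663. As many lists as the real 5 and 10 came in 20 and in 5 of the 100 splits, at most 12 in either. Apart from the real split, every split with so many genes kept most labels of 1 table and exchanged most of the other, so that the 2 effects, alike in direction for most genes, added up. That is a structure of these samples, and the gene counts of these splits therefore say little about chance either way.

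Without MPP+, genes that fell with knockdown rose with overexpression, HSP90AA1 and SIRT1 among them, in calls that rest on few libraries. With GC trends removed, the genes called in opposite directions were 5.72 times the overlap of independent lists. This argues against the GC trend that was removed as the whole cause. It cannot exclude GC bias that the removal missed, since genes are not independent and the annotation may differ from that of the authors. Both comparisons also share 1 estimate of each gene's spread, which can raise that ratio. Against gene length bias, or RNA degradation that follows length, transcript length correlated with fold change by only 0.0869 in size. For the calls lost with the trend, GC bias stays open: differences between replicates of 1 group followed GC content by up to 0.679. An axis along which replicates also differ, with GC trends removed, correlated with the overexpression minus knockdown change by 0.578 across genes, so sample handling or cell state that varies between replicates is a candidate explanation. An effect of MCART1 dose stays open too, as untested apart from these.

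Without MPP+, mitochondrial DNA-encoded mRNAs such as MT-ND2 were lower in oeMCART1 than in oeNC. Loss of GC trends left a median of -1.39, against GC bias as the cause. The median of oeMCART1 against shScramble was -0.0344, which is consistent with a high level in oeNC rather than a low one in oeMCART1; whether the oeNC construct, its cells or their handling raised it was not tested.

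SLC25A51 in untreated oeNC stood at 31.6 TPM, 20.7 TPM above shScramble. Reads of oeMCART1 spread evenly over the table would have raised the knockdown arm too, whose highest library stood at 11.2 TPM. For oeMCART1 RNA mixed into oeNC alone at 3.03%, 0 genes could decide, since none low in the knockdown arm would have reached 1 TPM. The bound written before the result rested on 8 such genes, 6 of them listed at 0 in oeNC, but their mixed-in levels would be 0.154 to 0.823 TPM, near the floor, so that bound was wrong. Treated oeNC stood at 8.49 TPM, near treated shScramble at 7.91 TPM, which argues against a level that is steadily higher in the oeNC cells; mixing into the untreated samples, which would lower the fold of 21.6, cannot be told apart from a level that MPP+ lowers.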

How the results depend on the processing

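Alternatives that remove trends on GC content or length, and for overlaps those that leave out libraries or groups, were chosen after seeing the data; the others were planned. Tests of MPP+ against untreated cells were not run, nor were their alternatives, since the tables share too few identifiers.

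Called genes for untreated knockdown (5035) numbered 1272 with no filter, 10110 with library weights, and 1241 with GC and 1225 with GC and length trends removed. With only the 2 groups compared limma called 0 (5799 at an unadjusted p under 0.05, smallest adjusted p = 0.0598). That fit called 7581 genes for untreated overexpression and 4994 and 8439 for treated knockdown and overexpression. Their full fits reached lower adjusted p, so fewer libraries stay open as the cause. For untreated overexpression (7082) called genes numbered 11287 with library weights and 2305 and 2316 with GC, or GC and length, trends removed. The knockdown difference (605) numbered 4619 with library weights and 1114 and 1167 with those trends removed, and the overexpression difference (2787) 6160 with library weights. With a replicate block the knockdown difference numbered 1097. Apart from the GC trend itself, the cause was not tested. The estimation of library weights stopped before it converged in some fits, so those counts are less certain.

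Leaving out 1 library at a time gave 2 to 7236 genes for untreated knockdown: 2233 without shMCART1 replicate 1, 960 without replicate 3 and 3178 without shScramble replicate 1. Without shScramble replicate 2 it gave 2, CA2 and PHEX-AS1. There 45 of 45 called named genes lost their call, and 5108 genes had an unadjusted p under 0.05. These 45 kept direction, at 0.778 to 1.33 times their log2 change. So did all 5035 called genes, in a fit that shares its other libraries with the full one. The range was 3989 to 7689 for untreated overexpression, the lowest without oeNC replicate 1, 3407 to 4587 and 8202 to 8697 for treated knockdown and overexpression, and 2196 to 2826 for the overexpression difference. For the knockdown difference it was 265 to 2464. Without untreated shMCART1 replicate 1, 2 or 3 the count was 355, 2464 or 350, and without untreated shScramble replicate 2 it was 268. Without treated shMCART1 replicate 1 or 2 it was 267 or 373, and without treated shScramble replicate 2 or 3 it was 380 or 265.

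SLC25A51 kept its direction in its 4 comparisons under every alternative run. Without MPP+ its knockdown call ended with no filter (-0.56, adjusted p = 0.0561) and with only the 2 groups compared (-0.56, 0.0758), and without shMCART1 replicate 1 (-0.54, 0.0518), shMCART1 replicate 3 (-0.39, 0.0625) or shScramble replicate 2 (-0.55, 0.0811). Over all alternatives the adjusted p ran from 5.11e-06 to 0.0811. Ranges without 1 library were -0.74 to -0.39 and, with MPP+, -0.58 to -0.44 for knockdown, and 4.35 to 4.48 and 6.57 to 6.70 for overexpression. The knockdown difference of SLC25A51, not called, changed sign to -0.0259 under median-of-ratios scaling, -0.0715 under quantile normalization and -0.00154 with GC and length trends removed. Without 1 library it ran from -0.0950 (shMCART1 replicate 3) to 0.251 (shMCART1 replicate 2), and stood at -0.0181 without treated shScramble replicate 1.

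Called lists for untreated knockdown (1, glycolysis) numbered 2 under median-of-ratios scaling, 0 by camera under quantile normalization (6 at an unadjusted p under 0.05), 5 with GC, and 5 with GC and length, trends removed, and 0 by camera with an estimated correlation (0 unadjusted). For untreated overexpression (3) they numbered 5 under quantile normalization, 6 with GC and 5 with GC and length trends removed, and 0 by camera with an estimated correlation (1 unadjusted). That correlation left 0 by camera of 9 for treated knockdown (6 unadjusted), 1 of 8 for treated overexpression, 1 of 5 for the knockdown and 2 of 10 for the overexpression difference. For treated overexpression the filter of 5 TPM and quantile normalization each ended 2 of the 8 list calls. The mitochondrial ribosome list turned downward with treated overexpression under median-of-ratios scaling (median 0.00916, adjusted p = 0.993). For that list the cause was not tested.

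Genes called in opposite directions (4114 and, with MPP+, 3906) numbered 581 and 2545 with GC, and 563 and 2547 with GC and length, trends removed. Genes shared with and without MPP+ numbered 552 and 545 for knockdown (2399) and 1136 and 1133 for overexpression (4801). With only the 2 groups of each comparison limma left 0 opposite genes without MPP+ (4870 unadjusted) and 0 shared knockdown genes (3274 unadjusted). Without 1 library the opposite genes ran from 1 to 5743 (1930 without shMCART1 replicate 1, 878 without shMCART1 replicate 3, 2680 without shScramble replicate 1, 1 without shScramble replicate 2) and, with MPP+, 2704 to 4008. The shared knockdown genes ran from 1 to 3025 (1281, 645 and 1 without untreated shMCART1 replicate 1, shMCART1 replicate 3 and shScramble replicate 2), the shared overexpression genes from 2908 (without untreated oeNC replicate 1) to 5239. With GC, and with GC and length, trends removed, the untreated knockdown changes of NDUFA9 (0.0275 and 0.0318), NDUFAF2 (0.29 and 0.29), MT-ATP6 (0.11 and 0.12) and MT-ND4 (0.0971 and 0.0922) and the knockdown difference of NDUFAF2 (-0.00704 and -0.0151) changed sign. Over 327 named gene results and 6313 values, 5942 kept direction and side of the threshold, 311 lost and 45 gained a call and 15 changed sign. Over 36 called lists and 320 values, 259 kept theirs, 60 lost the call and 1 turned.

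The 6 libraries of a comparison make 10 splits, the real split included, too few for a share under 0.05. As many genes came in 1 split in each of the 4 comparisons (highest others 1, 3, 1 and 1 genes, for knockdown and overexpression without, then with MPP+), and as many lists in 8, 5, 1 and 4 (highest others 5, 3, 6 and 9). Except for treated knockdown, splits with exchanged labels thus reached the real count of lists. The list counts of both untreated comparisons and of treated overexpression therefore do not stand out from such splits. For genes in opposite directions only the real split, 1 of 100, reached the count without MPP+ (highest other 7) and with it (highest other 1), and likewise for the shared knockdown (highest other 61) and overexpression effects (highest other 1). Since other splits of a comparison call at most 3 genes, overlaps that need them are near 0 whatever the cause, and this adds little to the counts above. Depth is unknown, so what it limits cannot be given.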

Other observations

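Tests of MPP+ were not run, and nothing in this part was tested. In the treated table the 13 mitochondrial DNA-encoded mRNAs stood at 0.285% of TPM in shScramble, 0.418% in shMCART1, 0.421% in oeNC and 0.724% in oeMCART1, against 4.90%, 4.58%, 8.70% and 4.44% in the untreated table. CHAC1, which degrades glutathione, stood at 3.74 TPM in untreated and 56.6 TPM in treated shScramble, and at 4.19 and 23.8 TPM in shMCART1. TRIB3 stood at 20.7 and 90.8 TPM in shMCART1 and at 13.1 and 228 TPM in oeMCART1. INSIG1 stood at 73.0 and 28.0 TPM in shScramble, 49.9 and 64.7 TPM in shMCART1, and 58.5 and 6.63 TPM in oeMCART1. The oeMCART1 levels of TRIB3 and INSIG1 stand here without those of their control, oeNC, and so show no effect of overexpression. Genes of the unfolded protein response of the endoplasmic reticulum stood lower in the treated table (median log2 difference -0.69 in shScramble, -0.37 in shMCART1, -0.99 in oeNC and -0.72 in oeMCART1), and glycolysis genes did too (-0.54, -0.62, -0.44 and -0.42). The 5 nuclear and long noncoding RNAs taken as a sign of RNA quality stood higher, by 1.66 in shScramble and 1.02 in oeMCART1. The median over all genes compared was -0.12, -0.01, -0.19 and -0.13.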
